A study of Homo sapiens with 41 samples.

How the data were processed

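RNA was sequenced from 41 samples in 15 groups: whole-cell RNA of A375, Colo800, UACC62 and H3122 cultures, and ribosome-bound RNA of A375 and A375R tumours grown in mice. Groups were taken from the sample titles and the characteristics in the labels. The titles divide A375R tumours in a pair of kinds, which were read, with the growth protocol in the labels, as A375R cells alone and as A375R mixed with A375 cells. Libraries were made with an Illumina TruSeq RNA kit, version 2, per the labels' protocols, which does not mark strand.

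Each of the 6 deposited tables holds 1 value per gene symbol and library, a signal that the authors made by dividing read counts by a size factor per library. The submitters' processing notes name STAR 2.3.0e, HTSeq 0.5.4, DESeq 1.18.0, and the builds hg19 and mm9, without the role of each. How reads from mouse cells were treated and which filters were used is not given in the sources used here. The deposited values were whole multiples of 1 step per library, so reads were recovered by dividing by that step: 100% of values came out whole within a tolerance of 0.1, the largest deviation being 0.00039. Recovered depth ran from 8063754 to 42843612 reads per library, with 16440 to 17844 genes detected, and deeper libraries have smaller counting error. Replicate pairs differed by more than sampling noise, with chi-square per degree of freedom from 1.3 to 52.8. Each sample was counted as 1 replicate, though this spread does not show that samples came from separate cultures or animals. The A375R table lists 21593 genes, and 23368 are listed in each of the others.

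The tables were normalised separately, and tests were run within a table. For each gene with a mean value of at least 10 over the libraries of its table, limma 3.58.1 in R 4.3.3 was run with a mean-variance trend on log2(value + 1), with all groups of the table in the fit. The threshold was a two-sided Benjamini-Hochberg adjusted p under 0.05. Log2 changes are on the log2(value + 1) scale, which understates the change of low genes. The tests, gene lists and rule for named genes were fixed before the data were examined. The genes listed in the 24 lists (576 members, 570 genes, 6 of them in 2 lists) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The lists cover MAPK output, AP-1, replication, mitosis, ribosome biogenesis, pigment cells, dedifferentiation and receptor kinases, cytokines, growth factors, extracellular matrix, interferon, FOXO, BCL2, cholesterol, glycolysis and hypoxia, oxidative phosphorylation, lysosome, ATF4 and heat shock, and markers of lung epithelium, leukocytes, endothelium, fibroblasts, and blood, skin and muscle. The ATF4 list also holds genes of the unfolded protein response.

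Named genes follow a rule. It takes, per comparison, the 10 largest changes in each direction among genes past the threshold with a mean of at least 50 and every library of one group above every library of the other (for the interaction, without this last condition). It adds up to 2 members of each list per direction with the smallest adjusted p, and always DUSP6, SPRY4, FOSL1, CCND1, MKI67, MITF, MLANA, AXL, IL6 and IGFBP3. Genes without a symbol and noncoding, antisense or pseudogene names were left out of the largest changes, by name pattern. Fewer genes are named than the rule takes. Which of them are named, and which list results are given, was decided after their values were seen and partly by how well the calls held, so the named genes are a sturdier selection than the rule's. Counts of genes that still passed under another setting, where said to be of the genes taken by the naming rule, are therefore over all changed genes the rule takes. Other such counts cover the named genes only, so they may make the calls look sturdier. For each gene said to have changed between 2 groups, every library of one group lay above every library of the other, unless stated. IL8, KIAA1199 and C10orf10 are the files' symbols. As the counting is not stated to use strand, a gene with an overlapping antisense gene, or a near-identical copy, is uncertain, as for the HLA family.

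Replicate numbers pair samples where every same-number pair correlates above 0.1 in the deviations from the group means. In A375 culture these were 0.567, 0.31 and 0.566 for vehicle with 6 h and 0.436, 0.197 and 0.41 for 6 h with 48 h, so the numbers pair those libraries. Vehicle with 48 h had a pair at 0.028 and fell short of this rule. As both pair with 6 h, pairing between them cannot be excluded. The main counts, SE and p-values come from fits without the block, and counts with the block are given beside them for A375 culture. The other tables showed no such pairing. Alternatives tried were pseudocounts of 0.5 and 5, no filter and a filter at 50, quantile normalisation, the replicate number as a block, a fit of the 2 groups alone, leaving out each library in turn, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 (Wald test) on the recovered reads. With quantile normalisation the median shift of the log2 change per gene was under 0.1 in each comparison, and single genes moved by more.

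The tests were tried on simulated counts with 200 changed genes, drawn from the real means and library sizes. At a 2-fold change limma recovered 64.2% of changed genes in the 6 h comparison of A375 (13816 genes run), 65.7% at 48 h, 38.8% between 48 h and 6 h. It recovered 92.5% in Colo800 (13451 genes), 94% in UACC62 (13649), 86.6% in H3122 (13959), 97% in A375 tumours (14069), and in A375R (13755 genes) 83.6% for the drug effect alone and 62.7% for the interaction.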

Results

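Gene expression was measured by RNA sequencing in 41 samples that the labels divide into 15 groups, deposited as 6 tables of normalised read counts per gene. The series asked how drug-sensitive melanoma and lung adenocarcinoma cells respond when their driver kinase is inhibited, and how drug-resistant cells respond to the tumour around them. A375, Colo800 and UACC62 are human melanoma lines and were given vemurafenib, an inhibitor of the mutant BRAF kinase, and H3122 is a human lung adenocarcinoma line that was given crizotinib, an inhibitor of the ALK kinase. In culture, whole-cell RNA was taken from A375 cells after vehicle or after 6 h or 48 h of vemurafenib at 0.1 µM (n = 3 each). It was also taken from Colo800 and UACC62 cells after vehicle or 48 h at 1 µM (n = 2 each), and from H3122 cells after vehicle or 48 h of crizotinib at 0.3 µM (n = 2 each). Tumours grown from A375 cells in mice received vehicle or 10 doses of vemurafenib at 75 mg/kg (n = 4 each), and from these the RNA bound to tagged ribosomes was isolated by immunoprecipitation with GFP beads. The same ribosome-bound RNA was taken from A375R, a vemurafenib-resistant derivative of A375 whose sample titles name the ribosomal protein RPL10a, in tumours whose labels read as A375R alone or as A375R mixed with drug-sensitive A375 cells, each under vehicle or vemurafenib (n = 3 each). The titles of mixed tumours set RPL10a beside A375R, but the labels do not spell out which cells of a mixed tumour carry the tag. It is an assumption that the values of mixed tumours are those of A375R cells. Depth ran from 9633599 to 12657149 reads per library in A375 culture, 13104124 to 14610564 in Colo800, 11441346 to 13996702 in UACC62, 12765857 to 14858024 in H3122, 8063754 to 25467614 in A375 tumours and 26884205 to 42843612 in A375R tumours. Levels are given as mean ± SD of normalised reads and log2 changes as estimate ± SE. The labels do not state that the samples of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

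The early response of A375 cells was read 6 h after vemurafenib. The transcripts that report MAPK signalling, the pathway the drug blocks, fell: SPRY4, a feedback inhibitor of receptor signalling, went from 4542 ± 1463 reads in vehicle to 168 ± 13.8 (log2 change -4.69 ± 0.24). DUSP6, a phosphatase that acts on ERK, went from 2793 ± 1100.2 to 408 ± 119 (-2.75 ± 0.27). EGR1 (-3.93 ± 0.51), an immediate early transcription factor, IER3 (-3.54 ± 0.16), an immediate early gene, FOSL1 (-1.66 ± 0.35), a subunit of AP-1, and CCND1 (-2.46 ± 0.32), which encodes cyclin D1, fell as well, and limma gave adjusted p = 4.81e-06 for SPRY4 and 0.00149 for CCND1. Of the MAPK output list, 21 of 23 fell (23 adjusted over the list alone), camera adjusted p = 3.5e-32 (adjusted p = 0.0147 with an estimated correlation). Of all list calls by camera in the 12 comparisons, this is the only one that held with an estimated correlation. Among the largest falls, UCN2, a secreted peptide of the CRF family, went from 955 ± 276 to 37.9 ± 2.93 (-4.58 ± 0.23), and the chemokine gene IL8 (the files' symbol for CXCL8) from 144 ± 6.11 to 8.30 ± 1.80 (-3.98 ± 0.32). FST (-3.44 ± 0.24), an activin antagonist, STC1 (-3.61 ± 0.56), a secreted glycoprotein, IGFBP3 (-2.93 ± 0.29), an IGF-binding protein, and IL11 (-2.73 ± 0.18), a cytokine, fell too.

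Of the cytokine and chemokine list, 5 of 13 fell (1 higher and 6 lower adjusted over the list alone), camera adjusted p = 0.000107 (adjusted p = 0.201 with an estimated correlation). Growth factors and their binding proteins went both ways, as 1 of 38 rose and 7 fell (4 and 9 adjusted over the list alone), camera adjusted p = 0.00246 (adjusted p = 0.357 with an estimated correlation). In the glycolysis and hypoxia list, 5 of 26 fell (10 adjusted over the list alone), camera adjusted p = 1.49e-07 (adjusted p = 0.0954 with an estimated correlation). In the AP-1 family, 4 of 11 fell (2 higher and 6 lower adjusted over the list alone), camera adjusted p = 0.00707 (adjusted p = 0.0954 with an estimated correlation). Among the rises, DCT, an enzyme of melanin synthesis, rose (3.35 ± 0.25) from 2.71 ± 0.499 reads. PHACTR1 (2.70 ± 0.39), a regulator of actin, CYP1B1 (2.29 ± 0.29), a cytochrome P450, SEMA3C (2.19 ± 0.30), a secreted semaphorin, and FGF1 (1.89 ± 0.28), a fibroblast growth factor, rose as well, as did BMF (1.28 ± 0.23), a pro-apoptotic member of the BCL2 family. The proliferation marker MKI67 stood at 0.26 ± 0.30 on the log2 scale against vehicle (limma adjusted p = 0.73). At 6 h limma called 0 of 28 mitosis genes, and 0 at an unadjusted p under 0.05, as did edgeR (0) and DESeq2 (0). For this list camera gave adjusted p = 0.0655, toward higher, and adjusted p = 0.0404 with the replicate number as a block and 0.00602 with quantile normalisation. In all, 608 of 13816 genes passed the limma test, 148 higher and 460 lower, 324 of them by at least 2-fold. With the replicate number as a block 1462 genes passed, and DESeq2 called 1045. Without vehicle replicate 2, vehicle replicate 3 or the 6 h replicate 2 the count was 315 (35), 385 (35) and 309 (35), of which 54, 74 and 43 were higher, with the number of the 46 changed genes taken by the naming rule that still passed in parentheses. The call of FOSL1 ended in a fit of the 2 groups alone (adjusted p = 0.0622), without vehicle replicate 1, 2 or 3 (adjusted p = 0.0669, 0.0592 and 0.073) and without the 6 h replicate 2 (adjusted p = 0.109).

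At 48 h, A375 cells differed from vehicle in 6903 of 13816 genes (3361 higher, 3542 lower, 3207 by at least 2-fold). With the replicate number as a block 8307 genes passed, 4099 higher and 4208 lower. Genes of the cell cycle fell together: MKI67 went from 3128 ± 1126 to 323 ± 79.1 reads (-3.24 ± 0.30, limma adjusted p = 1.82e-05). RRM2, a subunit of ribonucleotide reductase, went from 3505 ± 1283 to 210.3 ± 60.2 (-4.03 ± 0.27), and PLK1, a mitotic kinase, from 1965 ± 417 to 229 ± 21.1 (-3.08 ± 0.16). Of the mitosis list, 28 of 28 fell (28 adjusted over the list alone), camera adjusted p = 1.09e-17 (adjusted p = 0.291 with an estimated correlation). Among DNA replication genes, 27 of 27 fell (27 adjusted over the list alone), camera adjusted p = 7.64e-15 (adjusted p = 0.291 with an estimated correlation). Among those of ribosome biogenesis, 25 of 25 fell (25 adjusted over the list alone), camera adjusted p = 4.29e-12 (adjusted p = 0.258 with an estimated correlation). MAPK outputs were below vehicle, with SPRY4 at 142 ± 26.8 (-4.95 ± 0.24) and ETV4, an ETS transcription factor, at 56.9 ± 14.3 against 2978 ± 446 (-5.71 ± 0.21). Of that list 21 of 23 fell (21 adjusted over the list alone), camera adjusted p = 8.07e-10 (adjusted p = 0.258 with an estimated correlation). IGFBP3 fell from 4744 ± 1411 to 68.0 ± 17.1 (-6.08 ± 0.29), and INHBA (-4.36 ± 0.26), a subunit of activin, and IL11 (-4.25 ± 0.18) fell with it. The chemokine gene CCL2 rose from 8.66 ± 3.15 to 325 ± 191 (4.98 ± 0.42), MATN2, a matrix protein, from 3.29 ± 2.28 to 877 ± 334 (7.76 ± 0.64) and MGP, an inhibitor of calcification, from 62.5 ± 30.1 to 5893 ± 953 (6.63 ± 0.47).

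The melanocyte gene DCT rose at 48 h, reaching 2930.4 ± 612 reads from 2.71 ± 0.499 (9.61 ± 0.25). Of the pigment cell list, 8 of 16 rose and 1 fell (8 and 1 adjusted over the list alone), camera adjusted p = 0.00252 (adjusted p = 0.258 with an estimated correlation). JUN, a subunit of AP-1, rose from 359.6 ± 15.0 to 3035 ± 1032 (3.01 ± 0.30) and BMF by 3.34 ± 0.23, both past the limma threshold. Glycolytic genes were lower, with LDHA, lactate dehydrogenase, at 2943 ± 45.6 against 10017 ± 761 (-1.76 ± 0.12). In their list 2 of 26 rose and 20 fell (2 and 22 adjusted over the list alone), camera adjusted p = 2.58e-05 (adjusted p = 0.258 with an estimated correlation). Of the list of receptor tyrosine kinases and genes linked to dedifferentiation, 7 of 19 rose and 7 fell (7 and 7 adjusted over the list alone), camera adjusted p = 0.942, the mean of its log2 changes being above 0 and the median below. AXL, a receptor tyrosine kinase, changed by -0.91 ± 0.20 (limma adjusted p = 0.00296) and MITF, the melanocyte transcription factor, by 1.56 ± 0.31 (limma adjusted p = 0.00195).

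**Figure D1:**
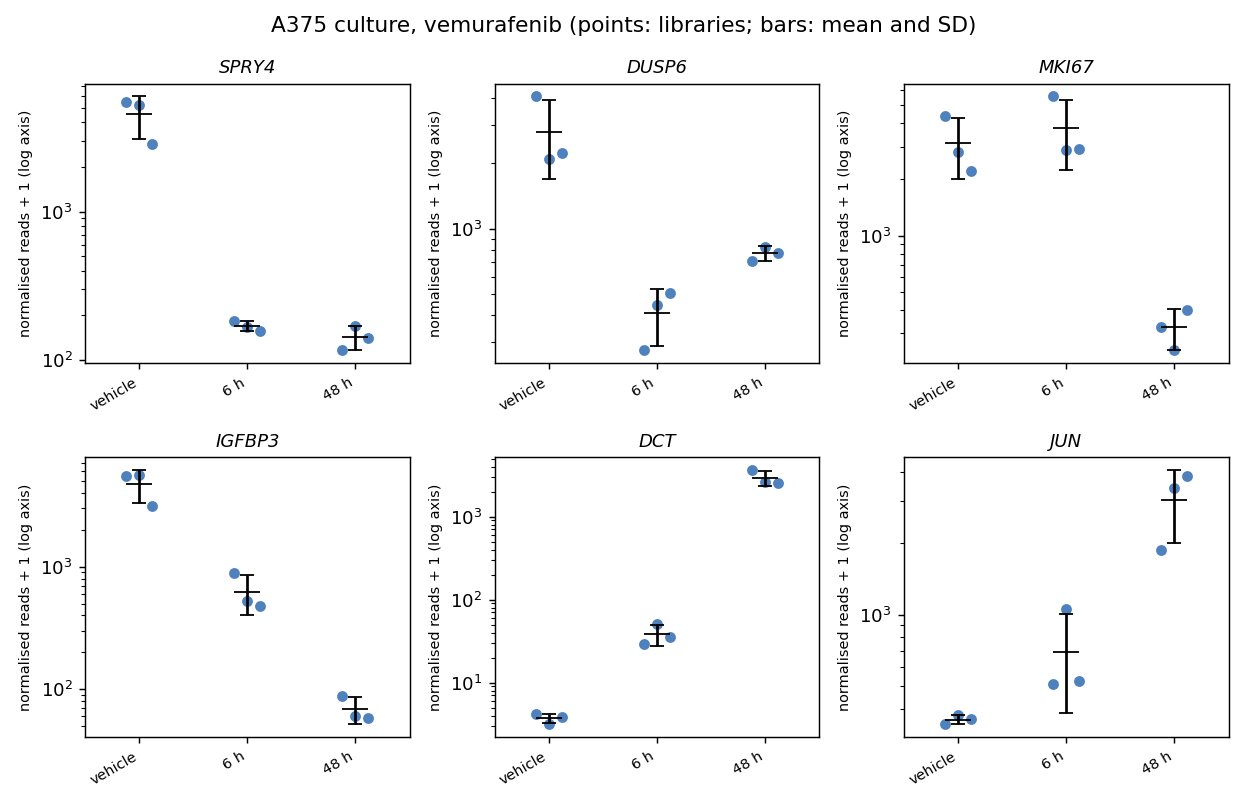
Normalised reads + 1 (log axis) of 6 genes in A375 culture for vehicle, 6 h and 48 h of vemurafenib, with a point per library and the mean and SD (n = 3 each). SPRY4 stood at 4542 ± 1463, 168 ± 13.8 and 142 ± 26.8 reads, and DCT at 2.71 ± 0.499 in vehicle and 2930.4 ± 612 at 48 h.

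The comparison of 48 h with 6 h asked which changes came later. RRM2 went from 3404 ± 846 at 6 h to 210.3 ± 60.2 at 48 h (-4.02 ± 0.27, limma adjusted p = 7.08e-06). MATN2 went from 7.27 ± 5.51 to 877 ± 334 (7.02 ± 0.64) and KIAA1199, a hyaluronan-binding protein, from 1179.9 ± 163 to 27.6 ± 5.59 (-5.37 ± 0.34). In the mitosis list, 28 of 28 fell (28 adjusted over the list alone), camera adjusted p = 1.49e-23 (adjusted p = 0.245 with an estimated correlation). In the extracellular matrix list, 15 of 31 rose and 5 fell (16 and 5 adjusted over the list alone), camera adjusted p = 0.0177 (adjusted p = 0.245 with an estimated correlation). Between these times 2 of 23 rose and 3 fell (2 and 2 adjusted over the list alone), camera adjusted p = 0.822 in the MAPK output list, with a median above 0 and a test direction below. SPRY4 stood at -0.26 ± 0.24 on the log2 scale (limma adjusted p = 0.416). In total 5427 genes differed, 2711 higher and 2716 lower at 48 h. With the replicate number as a block, which pairs these libraries, 6903 genes differed, 3471 higher and 3432 lower.

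Colo800 cells, another melanoma line, were compared after 48 h of vemurafenib (n = 2 each). SPRY4 fell from 4065 ± 43.5 to 46.9 ± 8.08 reads (-6.42 ± 0.091, limma adjusted p = 4.48e-20) and DUSP6 from 2924 ± 246 to 36.5 ± 2.80 (-6.29 ± 0.089). Of the MAPK output list 21 of 21 fell (21 adjusted over the list alone), camera adjusted p = 4.73e-15 (adjusted p = 0.154 with an estimated correlation). LIF (-7.47 ± 0.093), a cytokine, STC1 (-7.63 ± 0.13), IL8 (-5.89 ± 0.11), MMP1 (-4.77 ± 0.048), a collagenase, and THBS2 (-4.51 ± 0.041), a matrix glycoprotein, fell. Among cytokines and chemokines, 1 of 14 rose and 12 fell (1 and 12 adjusted over the list alone), camera adjusted p = 0.000133 (adjusted p = 0.193 with an estimated correlation). In the extracellular matrix list, 7 of 31 rose and 19 fell (7 and 19 adjusted over the list alone), camera adjusted p = 0.000449 (adjusted p = 0.193 with an estimated correlation). Of the genes of cholesterol synthesis, 22 of 22 fell (22 adjusted over the list alone), camera adjusted p = 2.36e-10 (adjusted p = 0.206 with an estimated correlation). RRM2 fell (-6.63 ± 0.078) with the DNA replication list, of which 27 of 27 fell (27 adjusted over the list alone), camera adjusted p = 2.68e-15 (adjusted p = 0.193 with an estimated correlation). Among the rises were KCNJ13, a potassium channel, from 7.07 ± 0.0498 to 1677 ± 139 (7.70 ± 0.14), EDNRB, the endothelin receptor of melanocytes (2.93 ± 0.041), MET, the receptor of hepatocyte growth factor (1.85 ± 0.056), and TXNIP, an inhibitor of thioredoxin (2.46 ± 0.045). In the pigment cell list 19 of 23 rose and 3 fell (19 and 3 adjusted over the list alone), camera adjusted p = 9.45e-07 (adjusted p = 0.406 with an estimated correlation). The limma test passed 9858 of 13451 genes, 4847 higher and 5011 lower, 2623 by at least 2-fold. The replicates of Colo800 lay near sampling noise, with chi-square per degree of freedom of 1.75 in vehicle and 1.77 under vemurafenib. The median SE was 0.0759, against 0.186 in A375 culture, so smaller changes passed here. With quantile normalisation 5679 were higher and 4261 lower, and 78 calls turned their direction.

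UACC62, a further melanoma line, was treated in the same way (n = 2 each). MKI67 fell from 1109 ± 26.5 to 2.02 ± 1.39 reads (-8.60 ± 0.30, limma adjusted p = 1.25e-07), RRM2 from 1871 ± 99.9 to 6.60 ± 0.553 (-7.94 ± 0.15), and SPRY4 from 7996 ± 178 to 26.9 ± 1.48 (-8.16 ± 0.11). For the mitosis list, 28 of 28 fell (28 adjusted over the list alone), camera adjusted p = 5.34e-21 (adjusted p = 0.26 with an estimated correlation). Of the MAPK outputs, 1 of 22 rose and 21 fell (1 and 21 adjusted over the list alone), camera adjusted p = 1.02e-11 (adjusted p = 0.26 with an estimated correlation). Pigment genes rose: DCT went from 228 ± 19.7 to 15734 ± 4475 (6.07 ± 0.17). PMEL, a structural protein of melanosomes, went from 22.0 ± 2.39 to 937 ± 88.3 (5.35 ± 0.15) and MLANA, a melanosome protein, from 968 ± 56.7 to 6854 ± 671 (2.82 ± 0.10). In the pigment cell list 15 of 20 rose and 3 fell (15 and 3 adjusted over the list alone), camera adjusted p = 1e-06 (adjusted p = 0.26 with an estimated correlation). MLANA lay under the filter on low values in A375, H3122 and A375R, as did IL6 in each table but A375R. NGFR, the low-affinity nerve growth factor receptor, rose by 3.29 ± 0.17 and BMF by 5.46 ± 0.14. Of the list of FOXO and PI3K-responsive genes, 16 of 27 rose and 5 fell (16 and 5 adjusted over the list alone), camera adjusted p = 0.0151 (adjusted p = 0.387 with an estimated correlation). IL8 fell (-3.44 ± 0.17). In the cholesterol synthesis list 18 of 22 fell (18 adjusted over the list alone), camera adjusted p = 1.8e-08 (adjusted p = 0.312 with an estimated correlation). The limma test passed 7707 of 13649 genes, 3668 higher and 4039 lower, 2856 by at least 2-fold. Chi-square per degree of freedom between the replicates was 1.3 in vehicle, near sampling noise, and 12.5 under vemurafenib. With quantile normalisation 4242 were higher and 3505 lower.

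H3122 lung adenocarcinoma cells showed the response to another driver inhibitor, crizotinib, after 48 h (n = 2 each). MAPK outputs fell here too: SPRY4 went from 1170.5 ± 46.0 to 195 ± 34.9 reads (-2.59 ± 0.12, limma adjusted p = 2.4e-08) and DUSP5, a nuclear ERK phosphatase, from 851 ± 23.2 to 45.7 ± 5.15 (-4.19 ± 0.13). Of that list, 1 of 22 rose and 21 fell (1 and 21 adjusted over the list alone), camera adjusted p = 6e-15 (adjusted p = 0.313 with an estimated correlation), the member that rose being MYC (0.61 ± 0.085), a transcription factor. EREG, an EGF receptor ligand, fell from 176 ± 20.8 to 6.60 ± 0.632 (-4.54 ± 0.24), and MMP1 (-5.88 ± 0.16), MUC2 (-5.75 ± 0.25), a secreted mucin, and PLAT (-4.16 ± 0.094), tissue plasminogen activator, fell as well. In the growth factor list, 4 of 35 rose and 18 fell (4 and 20 adjusted over the list alone), camera adjusted p = 0.000751 (adjusted p = 0.331 with an estimated correlation). Of the extracellular matrix list, 2 of 27 rose and 17 fell (3 and 17 adjusted over the list alone), camera adjusted p = 6.4e-06 (adjusted p = 0.313 with an estimated correlation). In the list of ATF4 and unfolded protein response genes, 16 of 22 fell (16 adjusted over the list alone), camera adjusted p = 9.63e-08 (adjusted p = 0.331 with an estimated correlation). Its members that fell included CHAC1, which degrades glutathione (-2.75 ± 0.14), and SLC7A11, the cystine transporter (-2.70 ± 0.13).

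Of the proliferation genes of H3122, MKI67 went from 5708 ± 672 to 4369 ± 501 (-0.39 ± 0.10, limma adjusted p = 0.0105), a call that ended with quantile normalisation (-0.21, adjusted p = 0.151), with no filter (adjusted p = 0.0855) and without crizotinib replicate 1 (-0.27, adjusted p = 0.187). In the mitosis list 22 of 28 fell (23 adjusted over the list alone), camera adjusted p = 6.17e-06 (adjusted p = 0.313 with an estimated correlation). Of the oxidative phosphorylation list, 11 of 26 fell (11 adjusted over the list alone), camera adjusted p = 0.000751 (adjusted p = 0.598 with an estimated correlation). That call ended with quantile normalisation (camera adjusted p = 0.058). Lung epithelial genes went both ways, 5 of 18 rose and 8 fell (5 and 8 adjusted over the list alone), camera adjusted p = 0.519. NKX2-1, the lineage transcription factor of lung, rose by 1.15 ± 0.083. TNFRSF19 (4.33 ± 0.17), a TNF receptor family member, BMP8A (4.25 ± 0.18), a bone morphogenetic protein, and IGFBP5 (3.19 ± 0.17), an IGF-binding protein, rose. Among genes of leukocytes and macrophages, 3 of 3 fell (3 adjusted over the list alone), camera adjusted p = 0.00129 (adjusted p = 0.331 with an estimated correlation). Of the endothelium list, 3 of 6 rose and 1 fell (3 and 1 adjusted over the list alone), camera adjusted p = 0.0543. The limma test passed 6436 of 13959 genes, 3086 higher and 3350 lower, 1423 by at least 2-fold.

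Across the cultures at 48 h, 3383 of 12386 genes tested in all 3 melanoma lines passed the limma test in the same direction in each, 1438 higher and 1945 lower. Independent lists of these sizes would share 288 and 371. With H3122 added, 1769 of 11804 genes moved alike (650 higher, 1119 lower, against 53.4 and 88.2). SPRY4 belongs to the genes that fell in all 4 lines, at -4.95, -6.42, -8.16 and -2.59 in A375, Colo800, UACC62 and H3122. FOSL1 does as well, at -3.30, -3.65, -2.55 and -2.73. These tables share no libraries and were normalised separately, so levels were not compared between them.

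Tumours of A375 cells in mice were compared after 10 doses of vemurafenib (n = 4 each). MAPK outputs were lower, with SPRY4 at 385 ± 123 reads against 7384 ± 851 (-4.31 ± 0.17, limma adjusted p = 1.19e-12). Of that list 20 of 23 fell (21 adjusted over the list alone), camera adjusted p = 1.11e-09 (adjusted p = 0.197 with an estimated correlation). Among the largest falls, PAEP, a secreted glycoprotein of the lipocalin family, went from 3039 ± 739 to 4.44 ± 2.06 (-9.17 ± 0.22). MMP1 went from 2359.9 ± 533 to 2.54 ± 1.74 (-9.58 ± 0.36) and EDN3, an endothelin, from 962 ± 219 to 1.60 ± 1.44 (-8.71 ± 0.34). IL11 (-4.04 ± 0.11) and the noncoding RNA H19 (-7.69 ± 0.20) fell with them. In the cytokine and chemokine list, 12 of 17 fell (1 higher and 12 lower adjusted over the list alone), camera adjusted p = 0.00611 (adjusted p = 0.278 with an estimated correlation). CCL2, which rose in culture at 48 h, fell in the tumours from 205 ± 44.5 to 31.3 ± 2.83 (-2.65 ± 0.16). SOX10, a transcription factor of the melanocyte lineage, rose from 785 ± 162 to 6775 ± 599 (3.13 ± 0.12) and ERBB3, the neuregulin receptor, from 449 ± 98.1 to 5846 ± 462 (3.72 ± 0.12). In the pigment cell list 9 of 12 rose and 1 fell (9 and 1 adjusted over the list alone), camera adjusted p = 0.00596 (adjusted p = 0.278 with an estimated correlation).

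In the same tumours, BMF (4.85 ± 0.13) and TXNIP (2.64 ± 0.10) rose. In the FOXO list 14 of 27 rose and 6 fell (14 and 6 adjusted over the list alone), camera adjusted p = 0.0188 (adjusted p = 0.43 with an estimated correlation). The BCL2 family went both ways, 4 of 12 rose and 5 fell (4 and 5 adjusted over the list alone), camera adjusted p = 0.928, with a median below 0 and a test direction above, which quantile normalisation turned (camera adjusted p = 0.985). For the mitosis list, 28 of 28 fell (28 adjusted over the list alone), camera adjusted p = 2.17e-11 (adjusted p = 0.312 with an estimated correlation). Among genes of cholesterol synthesis, 1 of 22 rose and 16 fell (1 and 18 adjusted over the list alone), camera adjusted p = 6.79e-06 (adjusted p = 0.278 with an estimated correlation). Of the leukocyte and macrophage list, 4 of 5 fell (5 adjusted over the list alone), camera adjusted p = 0.0227 (adjusted p = 0.278 with an estimated correlation). CSF1R, the macrophage growth factor receptor, went from 112 ± 23.0 to 6.86 ± 1.65 (-3.85 ± 0.23). Of the fibroblast and pericyte list, 6 of 14 rose and 4 fell (6 and 4 adjusted over the list alone), camera adjusted p = 0.928, with a median below 0 and a test direction above. In the endothelium list, 2 of 5 rose and 2 fell (2 and 2 adjusted over the list alone), camera adjusted p = 0.928. In the list for blood, skin and muscle, 2 of 4 rose (2 adjusted over the list alone), camera adjusted p = 0.333. How reads from mouse cells were handled is not given in the sources used here. The limma test passed 9603 of 14069 genes, 4815 higher and 4788 lower, 2964 by at least 2-fold. A375 culture at 48 h and A375 tumours changed alike in 4561 of 13350 genes, 2180 higher and 2381 lower, where independent lists would share 1110 and 1170.

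**Figure D2:**
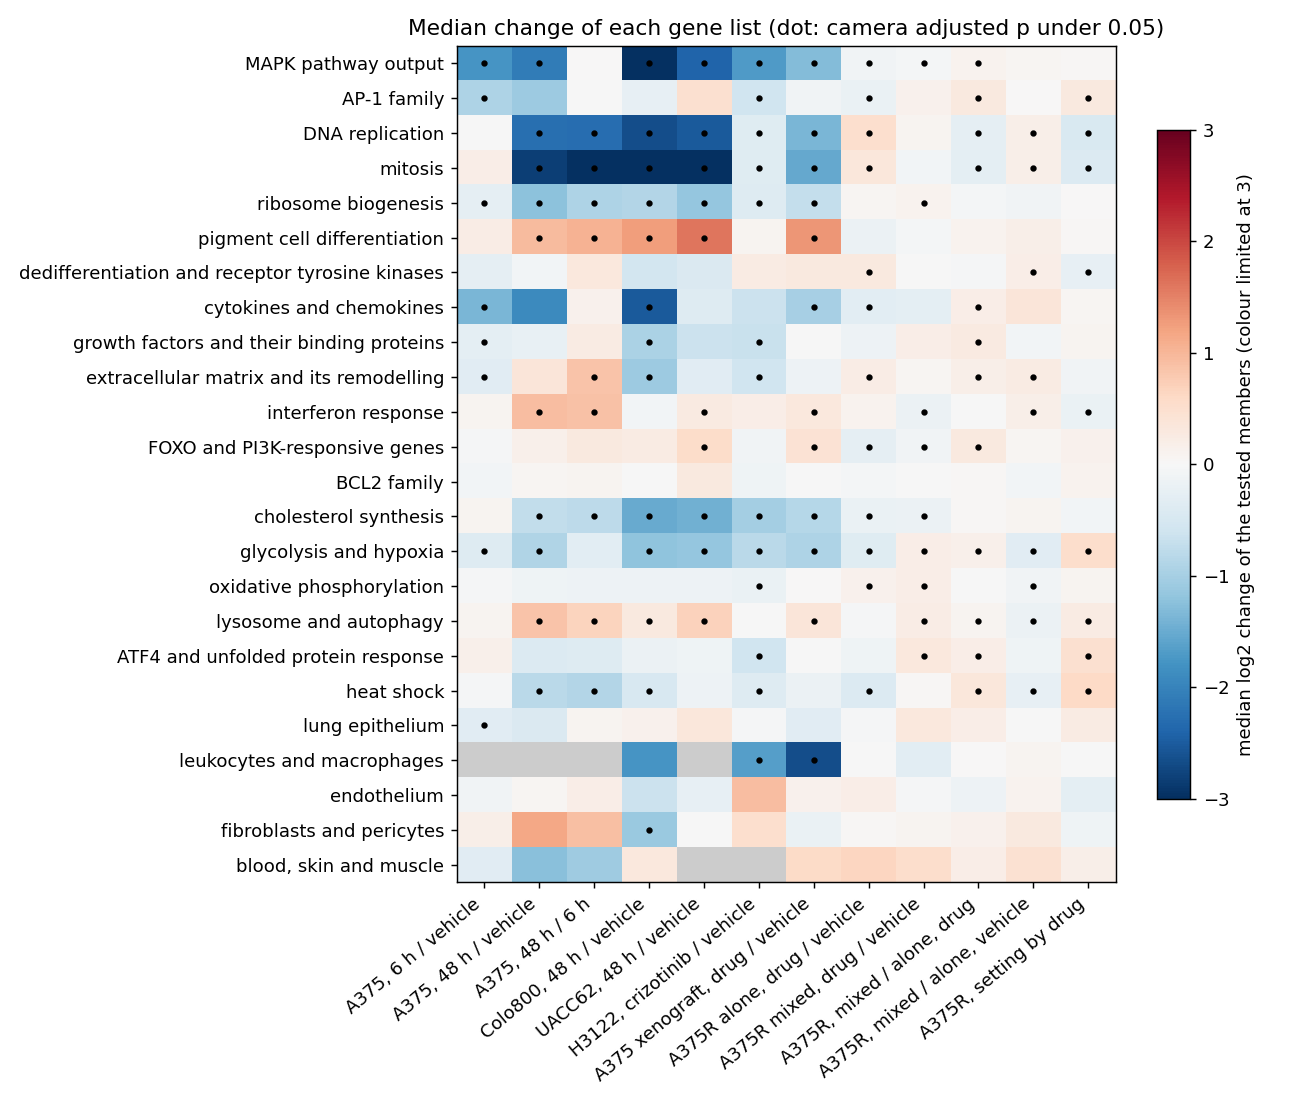
Median log2 change of the tested members of each gene list (rows) in each comparison (columns), with colour limited at 3 on the log2 scale, grey where under 3 members were tested, and a dot where the camera adjusted p was under 0.05. The mitosis list had a median of -2.83 in A375 culture at 48 h, -5.23 in UACC62 and -0.355 in H3122.

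Resistant A375R cells in tumours of their own were compared under vemurafenib and vehicle (n = 3 each), which addresses the response of resistant cells to the drug itself. Several genes fell: C10orf10, a stress-induced gene also called DEPP, went from 1523 ± 613 to 352 ± 138 reads (-2.09 ± 0.39, limma adjusted p = 0.0282). ALDOC, a glycolytic aldolase, went from 5389 ± 1048 to 2603 ± 331 (-1.04 ± 0.19) and ARRDC3, an arrestin-domain protein, from 1712 ± 383 to 533 ± 122 (-1.68 ± 0.24). Of the glycolysis and hypoxia list, 1 of 28 fell (11 adjusted over the list alone), camera adjusted p = 1.75e-07 (adjusted p = 0.515 with an estimated correlation). SPRY1 (-0.77 ± 0.17), a feedback inhibitor, and IER3 (-0.54 ± 0.12) fell. In the MAPK output list 3 of 23 fell (6 adjusted over the list alone), camera adjusted p = 0.00886 (adjusted p = 0.339 with an estimated correlation). MCM5 (0.72 ± 0.14) and MCM6 (0.91 ± 0.15), subunits of the replicative helicase, rose. In the DNA replication list 6 of 27 rose (22 adjusted over the list alone), camera adjusted p = 2.59e-17 (adjusted p = 0.339 with an estimated correlation). DUSP6 stood at -0.39 ± 0.14 (limma adjusted p = 0.149) and FOSL1 at 0.18 ± 0.14 (limma adjusted p = 0.507), neither past the threshold. TMEM98 (2.16 ± 0.42), a membrane protein, FST (1.09 ± 0.14) and COL1A1, a collagen chain (1.08 ± 0.17), rose as well. In total 109 of 13755 genes passed the limma test, 42 higher and 67 lower, 25 by at least 2-fold. DESeq2 called 755, a fit of these groups alone 530 and a fit with no filter on low values 14, with 4 of the 27 changed genes taken by the naming rule. The fit with no filter ended the calls of C10orf10, ALDOC, SPRY1, IER3, MCM5 and TMEM98, edgeR those of SPRY1 and IER3, and quantile normalisation that of SPRY1, at adjusted p from 0.0501 to 0.0876. Without vehicle replicate 1, 2 or 3 the count was 3 (2), 33 (12) and 1 (0), with the number of those genes that still passed in parentheses, and without vemurafenib replicate 1, 2 or 3 it was 4 (2), 2 (2) and 326 (25). Without vehicle replicate 3 none of the 10 genes named here as changed passed (adjusted p from 0.0609 to 0.257). Of the 10, FST and MCM6 still passed without vehicle replicate 1, FST without vemurafenib replicate 1, and FST and ARRDC3 without vemurafenib replicate 2, while IER3, MCM5, SPRY1 and TMEM98 did not pass without vehicle replicate 2 and IER3 did not without vemurafenib replicate 3.

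In the mixed tumours the drug comparison asked how A375R cells respond when drug-sensitive neighbours are treated (n = 3 each). Several genes fell under vemurafenib: SLC24A3, a cation exchanger, went from 243 ± 116 to 3.72 ± 0.308 reads (-5.60 ± 0.48, limma adjusted p = 1.49e-05). SOX10, the neural crest transcription factor, went from 789 ± 260.0 to 135 ± 104 (-2.75 ± 0.52), and SERPINA3, a secreted protease inhibitor, from 389 ± 315 to 48.4 ± 9.22 (-2.70 ± 0.43). SPRY4 (-0.81 ± 0.13) and TGFA, an EGF receptor ligand (-1.96 ± 0.32), fell. In the MAPK output list 5 of 23 fell (7 adjusted over the list alone), camera adjusted p = 0.0487 (adjusted p = 0.579 with an estimated correlation). MGP rose from 42.8 ± 4.48 to 293 ± 221 (2.45 ± 0.56), CRABP2, which binds retinoic acid, by 2.11 ± 0.28, FST by 1.42 ± 0.14, and IL18, a cytokine, by 1.95 ± 0.42. In the lysosome and autophagy list, 3 of 27 rose (6 adjusted over the list alone), camera adjusted p = 0.000895 (adjusted p = 0.579 with an estimated correlation). In the oxidative phosphorylation list, 3 of 26 rose (11 adjusted over the list alone), camera adjusted p = 2.94e-05 (adjusted p = 0.579 with an estimated correlation). In total 478 of 13755 genes passed, 171 higher and 307 lower, 144 by at least 2-fold. Genes abundant in A375 tumours and nearly absent from A375R tumours alone were set against their level in A375 vehicle tumours. The tables were normalised separately, and each library was scaled to the same total. In the mixed vehicle libraries these genes stood at a median of 6.11%, 1.74% and 2.25% of that level. In the mixed vemurafenib libraries they stood at 0.277%, 0.0831% and 0.214% of the same vehicle level. Among the 14 most abundant of these genes, GAS7 and TFAP2B were higher in A375 tumours under vemurafenib than under vehicle, and the others were lower. The smaller shares under vemurafenib therefore cannot separate less RNA of A375 cells from the drug response of these genes. Leaving out, in a test chosen after the data were seen, all genes at least 2-fold higher in A375 than in A375R tumours left 88 changed genes, 63 higher and 25 lower. SLC24A3, SOX10, SERPINA3, SPRY4, TGFA, CRABP2 and IL18 are among the genes left out. DESeq2 called 958 genes and a fit of these groups alone 229, of which 47 were higher. Without mixed vehicle replicate 1 the count was 105 (22), 23 of them higher, and, without mixed vemurafenib replicates 1, 2 and 3, 378 (42), 240 (36) and 255 (35), with the number of the 47 changed genes taken by the naming rule that still passed in parentheses. Of the counts without a mixed vemurafenib replicate, 178, 55 and 65 genes were higher. MGP and IL18 did not pass without mixed vehicle replicate 1 (adjusted p = 0.105 and 0.0698), mixed vemurafenib replicate 1 (adjusted p = 0.0559 and 0.0635) or mixed vemurafenib replicate 3 (adjusted p = 0.0958 and 0.0563), and SOX10 did not without mixed vehicle replicate 1 (adjusted p = 0.0644).

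Under vemurafenib, mixed tumours differed from A375R alone in 33 genes, 29 higher and 4 lower, a contrast of the tumour settings under the same drug. It cannot separate an effect of treated neighbours from RNA of A375 cells in the mixed tumours. DUSP1, a stress-induced phosphatase, stood at 1639.7 ± 183 reads in mixed against 622 ± 185 in alone tumours (1.43 ± 0.22, limma adjusted p = 0.0107). ARRDC3 stood at 1404 ± 544 against 533 ± 122 (1.34 ± 0.24), and DDIT3, the stress factor CHOP, at 2637 ± 485 against 1370.3 ± 346 (0.96 ± 0.18). The cytokine genes TSLP (1.48 ± 0.22) and IL18 (2.39 ± 0.42) and SERPINA3 (2.64 ± 0.43) were higher. Of the cytokine and chemokine list, 2 of 21 were higher (3 adjusted over the list alone), camera adjusted p = 0.00098 (adjusted p = 0.104 with an estimated correlation). In the list of ATF4 and unfolded protein response genes, 1 of 22 was higher (3 adjusted over the list alone), camera adjusted p = 1.33e-05 (adjusted p = 0.269 with an estimated correlation). FOS, a subunit of AP-1, stood at 1190.2 ± 419.9 against 291 ± 99.5 (2.01 ± 0.40, limma adjusted p = 0.0498). The call of FOS ended with either other pseudocount or filter, quantile normalisation, edgeR, the genes higher in A375 left out, and any 1 library left out except mixed replicate 1, at adjusted p from 0.0501 to 0.229. In the AP-1 family, 1 of 12 was higher (5 adjusted over the list alone), camera adjusted p = 0.00123 (adjusted p = 0.269 with an estimated correlation). MPP4, a scaffold protein, was lower, 242 ± 39.3 against 467 ± 111 (-0.93 ± 0.17). DESeq2 called 151 genes (111 higher, 40 lower), edgeR 13 (10 higher, 3 lower), no filter 11, quantile normalisation 10, a fit of these groups alone 8, and a fit without the genes higher in A375, chosen after the data were seen, 14, with ARRDC3, IL18 and SERPINA3 among the genes left out. Without alone replicates 1, 2 and 3 the count was 1 (0), 2 (1) and 38 (11), with the number of the 16 changed genes taken by the naming rule that still passed in parentheses, and without mixed replicates 1, 2 and 3 it was 31 (10), 21 (9) and 1 (0). None of the 8 genes named here as different passed without alone replicate 1 (adjusted p from 0.0758 to 0.229) or mixed replicate 3 (adjusted p from 0.0618 to 0.186), and of them DUSP1 alone passed without alone replicate 2. ARRDC3 did not pass without alone replicate 3 or mixed replicate 2, DDIT3 without mixed replicate 2, and IL18 and MPP4 without mixed replicate 1. The calls of ARRDC3, DDIT3, IL18 and MPP4 also ended with no filter, quantile normalisation and a fit of these groups alone, that of TSLP in this last fit, and those of DDIT3 and SERPINA3 with edgeR, at adjusted p from 0.0514 to 0.132.

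Under vehicle, mixed tumours differed from A375R alone in 454 of 13755 genes, 266 higher and 188 lower (203 by at least 2-fold), a contrast of the tumour settings without drug. SOX10 stood at 789 ± 260.0 reads in mixed tumours, against 101 ± 39.3 in alone tumours (2.99 ± 0.52, limma adjusted p = 0.0043), SERPINA3 at 389 ± 315 against 4.85 ± 0.980 (5.78 ± 0.43) and GAS7, a cytoskeletal regulator, at 359.9 ± 181 against 13.7 ± 4.02 (4.54 ± 0.40). MMP9 (2.91 ± 0.45), a gelatinase, IFIT1 (1.59 ± 0.24) and MX1 (1.25 ± 0.19), interferon-induced antiviral genes, were higher too. Of the interferon list, 4 of 32 were higher (6 adjusted over the list alone), camera adjusted p = 0.000232 (adjusted p = 0.694 with an estimated correlation). In the extracellular matrix list, 6 of 37 were higher (10 higher and 2 lower adjusted over the list alone), camera adjusted p = 0.0175 (adjusted p = 0.694 with an estimated correlation). C10orf10 (-1.70 ± 0.39), IL24, a cytokine (-1.61 ± 0.33), and EPHB6, an ephrin receptor (-1.68 ± 0.27), were lower, as was the glycolytic aldolase ALDOA (-0.68 ± 0.17, limma adjusted p = 0.0356). The call of ALDOA ended with quantile normalisation (-0.20, adjusted p = 0.472), no filter (adjusted p = 0.0799), a fit of these groups alone (adjusted p = 0.0575) and without the genes higher in A375 (adjusted p = 0.0582). It also ended without alone replicate 1, alone replicate 3 or mixed replicate 1 (adjusted p = 0.207, 0.152 and 0.148). The calls of C10orf10 and IL24 ended without the same libraries (adjusted p = 0.146, 0.117 and 0.16 for C10orf10 and 0.078, 0.0693 and 0.0763 for IL24), and that of C10orf10 also without the genes higher in A375 (adjusted p = 0.0515). In the glycolysis and hypoxia list 3 of 28 were lower (13 adjusted over the list alone), camera adjusted p = 1.52e-07 (adjusted p = 0.694 with an estimated correlation). The genes abundant in A375 and nearly absent from A375R alone, picked without the mixed libraries, stood at medians of 6.11%, 1.74% and 2.25% of their A375 level in mixed and -0.0369%, 0.0478% and -0.0305% in alone vehicle libraries, the mean of the alone libraries being subtracted. Of the 264 higher genes listed in both tables, 236 (89.4%) were at least 2-fold higher in A375 than in A375R tumours alone, as were 33.3% of all tested genes listed in both and 9 of 187 lower genes. Without such genes 73 genes passed, 18 higher and 55 lower. SOX10, SERPINA3, GAS7, MMP9, IFIT1, MX1 and EPHB6 are among the genes left out there. A filter at a mean of 50 gave 297 genes and DESeq2 870. Without alone replicates 1 and 3 and without mixed replicate 1 the count was 166 (22), 150 (20) and 124 (20), with the number of the 37 changed genes taken by the naming rule that still passed in parentheses. Of these counts 27, 12 and 17 genes were lower, so the lower calls depended on these libraries more than the higher ones.

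**Figure D3:**
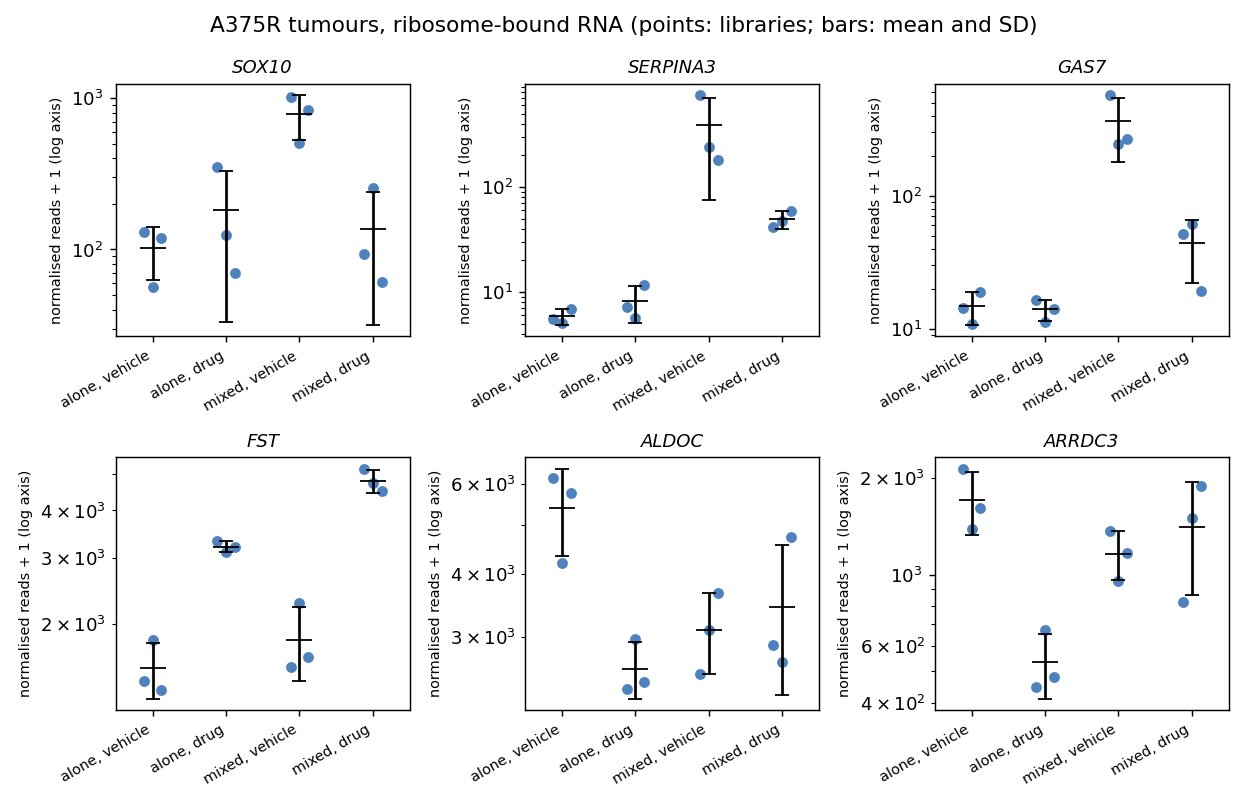
Normalised reads + 1 (log axis) of 6 genes in the 4 groups of A375R tumours, with a point per library and the mean and SD (n = 3 each). SERPINA3 stood at 4.85 ± 0.980 reads in alone vehicle, 389 ± 315 in mixed vehicle and 48.4 ± 9.22 in mixed vemurafenib tumours.

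The interaction asked whether the drug response of A375R differed between mixed and alone tumours. The drug effect was lower in mixed tumours for SOX10, by -3.35 ± 0.74 on the log2 scale (limma adjusted p = 0.0282), and for SERPINA3 (-3.14 ± 0.61), and higher for C10orf10 (3.07 ± 0.55), ARRDC3 (1.89 ± 0.34) and ADM, the hypoxia-induced peptide adrenomedullin (1.65 ± 0.34). Of the glycolysis and hypoxia list, 3 of 28 were higher (10 adjusted over the list alone), camera adjusted p = 9.36e-08 (adjusted p = 0.553 with an estimated correlation). In the heat shock list, 2 of 14 were higher (3 adjusted over the list alone), camera adjusted p = 0.000668 (adjusted p = 0.553 with an estimated correlation), a call that quantile normalisation ended (camera adjusted p = 0.0521). In total 397 genes passed, 263 with a higher and 134 with a lower drug effect in mixed tumours. Without the genes higher in A375, which include SOX10, SERPINA3 and ARRDC3, 341 passed, 306 with a higher and 35 with a lower effect. No filter gave 185 genes and DESeq2 887, and no filter ended the call of SOX10 (adjusted p = 0.0523) and edgeR that of SERPINA3 (adjusted p = 0.0602). None of the 5 genes named here passed without alone vehicle replicate 1 (adjusted p from 0.0611 to 0.0689) or alone vehicle replicate 3 (adjusted p from 0.0604 to 0.0788). ADM, C10orf10 and SOX10 did not pass without mixed vehicle replicate 1, and SOX10 did not without alone vehicle 2, alone vemurafenib 1 or 2 or mixed vemurafenib 3 (adjusted p from 0.0509 to 0.0739 over these libraries). Leaving out alone vehicle replicates 1, 2 and 3 gave 15 (4), 221 (28) and 10 (3), with the number of the 45 changed genes taken by the naming rule that still passed in parentheses, alone vemurafenib 1 and 2 gave 150 (21) and 48 (13), mixed vehicle 1 gave 41 (9), and mixed vemurafenib 2 and 3 gave 159 (25) and 70 (16). The drug effect was higher in 4 of the genes without alone vehicle replicate 1 and in 2 without replicate 3.

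**Figure D4:**
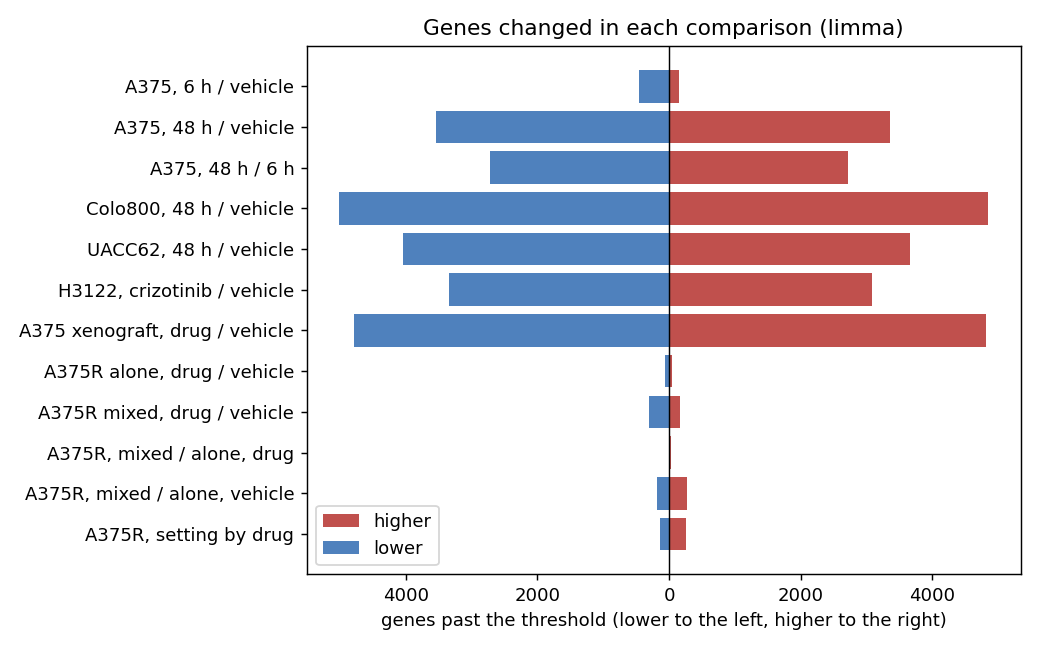
Genes past the limma threshold in each of the 12 comparisons, lower to the left and higher to the right of 0. Colo800 had the longest bars (9858 genes) and mixed against alone under vemurafenib the shortest (33). By at least 2-fold, Colo800 had 2623 genes and A375 culture at 48 h had 3207, so bar length also follows the spread between replicates.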

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

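The tests in this part were fixed before their results were seen, and the opposite directions described for CCL2 and SOX10 were noticed afterwards and not tested.

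In A375 tumours under vemurafenib, CCL2 stood at 35.5 reads in replicate 2 and at 29.6 to 30.3 in the others, and the gap of that library to the nearest, divided by the range, was 0.884. In the same group CRYAB stood at 137 in replicate 1 and 86.2 to 94.4 in the others (0.839), and CTSD at 2084 in replicate 4 and 2492 to 2527 in the others (0.922). HLA-E stood at 939.99 in vehicle replicate 3 and 1111 to 1143 in the others (0.843). These are 4 of 34 checks of a named gene in a group of 4 samples (11.8%), and chance alone puts about 1 in 20 groups past this limit.

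The response of A375 to vemurafenib differed between times in 5427 genes by limma, among them KIAA1199 (-5.37), MATN2 (7.02) and RRM2 (-4.02) on the log2 scale at 48 h against 6 h. The drug effect on A375R differed between mixed and alone tumours in 397 genes, with log2 differences of 1.65 for ADM, 1.89 for ARRDC3, 3.07 for C10orf10, -3.14 for SERPINA3 and -3.35 for SOX10. ARRDC3, SERPINA3 and SOX10 are among the genes at least 2-fold higher in A375 than in A375R tumours. RNA of A375 cells in the mixed tumours may take part in their values. None of the 5 genes passed without alone vehicle replicate 1 or 3.

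On the log2 scale CCL2 changed by 4.98 in A375 culture at 48 h and by -2.65 in A375 tumours, with no overlap between the libraries of drug and vehicle in either. SOX10 changed by 3.13 in A375 tumours and by -2.75 in mixed A375R tumours, where RNA of A375 cells may take part in its values. Neither of these differences was tested.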

How the results depend on the processing

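The alternative without A375-type genes and the crossed pairing were chosen after the data were seen, and all other settings were planned. Of 2219 values of named genes under the alternatives, 2069 kept direction and side of the threshold, 149 lost the threshold and 1 reversed. These genes were chosen after their values were seen, so the share kept may be too high. Of all changed genes the rule takes, 4 of 27 passed with no filter in A375R alone. In mixed against alone under drug 5 of 16 passed with quantile normalisation, while in A375 culture at 48 h 98 of 99 passed with either setting. Of 216 values of gene lists 147 kept direction and side of the threshold, 64 lost it (61 of them with an estimated correlation), 3 gained it and 2 reversed. The cause was not tested for any of the values that follow, except that leaving out libraries or genes takes them from the test. MKI67 at 6 h in A375, which did not pass, reversed to -0.055 without 6 h replicate 1 (range without 1 library -0.055 to 0.534). The dedifferentiation and receptor kinase list at 48 h reversed with the replicate block (camera adjusted p = 0.997), and the BCL2 list in A375 tumours with quantile normalisation (camera adjusted p = 0.985), neither past the threshold in any setting.

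Counts of changed genes moved by more than 1.5 times in the following cases. DESeq2 called 1045 for A375 at 6 h, 755 for A375R alone, 958 for A375R mixed, 151 for mixed against alone under drug, 870 under vehicle and 887 for the interaction. With the replicate block the count was 1462 for A375 at 6 h, 298 for A375R alone and 65 for mixed against alone under drug. A fit of the 2 groups gave 530 for A375R alone, 229 for A375R mixed and 8 for mixed against alone under drug. No filter gave 14 for A375R alone, 11 for mixed against alone under drug and 185 for the interaction, and a filter at 50 gave 297 for mixed against alone under vehicle. Quantile normalisation gave 10 and edgeR 13 for mixed against alone under drug. Without the A375-type genes the count was 88 for A375R mixed, 14 for mixed against alone under drug and 73 under vehicle.

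Leaving out 1 library gave 309 to 640 genes for A375 at 6 h, 5869 to 6414 genes at 48 h and 4292 to 4810 genes for 48 h against 6 h. It gave 9022 to 9297 genes in Colo800, 5245 to 9874 genes in UACC62, 4331 to 6913 genes in H3122 and 9051 to 9387 genes in A375 tumours. It gave 1 to 326 genes in A375R alone, 105 to 562 genes in A375R mixed, 1 to 38 genes for mixed against alone under drug, 124 to 668 genes under vehicle and 10 to 539 for the interaction. Where a group of 2 kept 1 sample, that sample was assumed to vary like the others. The replicate block changed the mitosis list at 6 h (camera adjusted p = 0.0404), the endothelium list in H3122 (camera adjusted p = 0.000572) and the MAPK list in A375R mixed (camera adjusted p = 0.0619). Among the list results given here it changed no other call, other than the reversal given above, and it changed no call of a named gene. In tables whose numbers do not pair the samples, same-number correlations ran from -0.125 to 0.0419 in A375 tumours, -0.205 to 0.261 in A375R, and were 0.0266 in Colo800, 0.0167 in UACC62 and -0.209 in H3122, where crossed pairing called 8522 genes. With quantile normalisation more genes were higher than lower where the reverse held before, in Colo800 (5679 and 4261), UACC62 (4242 and 3505), H3122 (3081 and 2923) and A375 at 48 h (3396 and 3384). It changed the mitosis list at 6 h (camera adjusted p = 0.00602), oxidative phosphorylation in H3122 (camera adjusted p = 0.058) and heat shock in the interaction (camera adjusted p = 0.0521). At the depth and spread of these libraries a 1.5-fold change was recovered for 11.9% of simulated genes in A375 at 6 h. The share was also 11.9% in the interaction, so changes of that size were mostly not detectable in either. It was 5.97% in A375 at 48 h and 7.46% for 48 h against 6 h. These 48 h shares cannot tell how many real changes of that size were detectable. The simulation held far fewer changed genes than passed there, which makes its adjusted p stricter. Of the 6903 genes that passed at 48 h, 3207 changed by at least 2-fold, as did 2272 of 5427 between the times, so many smaller changes passed. In the other comparisons 40.3% (A375R alone) to 89.6% (Colo800) were recovered.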

Other observations

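The carry-over, size-factor and library-size tests described here were chosen after the result was seen, and the counts of other splits and the test without each alone vehicle library were planned.

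Interferon genes rose in A375 at 48 h: IRF9, a transcription factor of that response, rose by 1.84 ± 0.14 (limma adjusted p = 6.5e-06). DDX58, an RNA sensor, rose by 2.29 ± 0.18, and ISG20, an exonuclease, fell (-2.61 ± 0.37). Of the interferon list, 25 of 31 rose and 1 fell (26 and 1 adjusted over the list alone), camera adjusted p = 1.1e-07 (adjusted p = 0.258 with an estimated correlation). In UACC62 STAT2, a signal transducer of interferon, rose by 2.07 ± 0.093 and OAS3, an antiviral enzyme, fell (-1.46 ± 0.17). In the interferon list of UACC62, 16 of 31 rose and 4 fell (16 and 4 adjusted over the list alone), camera adjusted p = 0.0139 (adjusted p = 0.599 with an estimated correlation). For that list in Colo800, 10 of 30 rose and 12 fell (10 and 12 adjusted over the list alone), camera adjusted p = 0.892, with a median and mean below 0 and a test direction above. In A375 tumours HLA-C and HLA-E, which present antigen, rose by 0.95 ± 0.088 and 0.90 ± 0.076. For the interferon list there, 16 of 33 rose and 4 fell (16 and 4 adjusted over the list alone), camera adjusted p = 0.0416 (adjusted p = 0.821 with an estimated correlation).

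More genes of the lysosome list rose than fell in the 3 melanoma lines at 48 h and in A375 tumours. CTSD, a lysosomal protease, rose by 1.65 ± 0.092 in UACC62 and by 1.33 ± 0.093 in A375 tumours, and PSAP, a lysosomal cofactor, by 1.23 ± 0.044 in Colo800. Of the lysosome list in A375 at 48 h, 14 of 27 rose and 2 fell (14 and 2 adjusted over the list alone), camera adjusted p = 0.000801 (adjusted p = 0.578 with an estimated correlation). For Colo800, 18 of 27 rose and 8 fell (18 and 8 adjusted over the list alone), camera adjusted p = 0.0312 (adjusted p = 0.273 with an estimated correlation). Of that list in UACC62, 19 of 27 rose and 2 fell (20 and 3 adjusted over the list alone), camera adjusted p = 3.61e-06 (adjusted p = 0.389 with an estimated correlation). In A375 tumours 19 of 27 rose and 3 fell (19 and 3 adjusted over the list alone), camera adjusted p = 0.00596 (adjusted p = 0.695 with an estimated correlation). Among heat shock genes, HSPD1, a mitochondrial chaperone, fell in A375 (-1.31 ± 0.14), Colo800 (-1.22 ± 0.039) and UACC62 (-1.58 ± 0.084), while CRYAB, a small chaperone, rose in Colo800 (3.37 ± 0.083), UACC62 (3.77 ± 0.10) and A375 tumours (4.36 ± 0.25). Of the heat shock list in A375 at 48 h, 1 of 14 rose and 10 fell (1 and 11 adjusted over the list alone), camera adjusted p = 0.00252 (adjusted p = 0.41 with an estimated correlation). Of the same list in H3122, 10 of 13 fell (10 adjusted over the list alone), camera adjusted p = 0.00104 (adjusted p = 0.426 with an estimated correlation). NOP56, a nucleolar protein of ribosome biogenesis, fell in Colo800 (-1.01 ± 0.045) and in A375 tumours (-1.30 ± 0.071). Of the ribosome biogenesis list in A375 tumours, 2 of 25 rose and 19 fell (2 and 20 adjusted over the list alone), camera adjusted p = 3.23e-05 (adjusted p = 0.278 with an estimated correlation).

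Of 264 genes higher in mixed than in alone vehicle tumours, 236 (89.4%) were at least 2-fold higher in A375 than in A375R alone, against 33.3% of all genes and 9 of 187 lower genes, and 229 against 30.9% with a reference added after the values were seen, the alone vemurafenib tumours, which this contrast does not use, and a candidate explanation is RNA of A375 cells in the mixed tumours. Of 108 genes abundant in A375 and nearly absent from A375R alone, picked without the mixed libraries, 101 (93.5%) were higher in mixed tumours, at a median of 3.34% of their A375 level and with 1 of the 14 most abundant under 0.1 times that median, against 386 of 704 control genes (54.8%). The 236 stood at a median of 14.5% (quartiles 8.6 to 23). The genes of this type called without mixed vehicle replicate 1, 2 or 3 stood in that library at 23.9%, 5.74% and 8.24%. The picked genes stood there at 6.11%, 1.74% and 2.25%. These values go against such RNA, at the same share for every gene, as the whole source. Calling favours genes with a large share, so where the share varies between genes these values cannot argue against such RNA. With the 104 genes also present in the other lines kept in, 182 of 212 (85.8%) were higher. Of the 35 most abundant of these, 13 lay under 0.1 of the median, which also goes against the same share for every gene. Such RNA stays open as an explanation, and the quartiles of called and picked genes overlapped in replicate 2. Of those 13 genes, 12 were present in each of the 4 other lines, so that the A375R table may have counted them differently. At its level in A375 vehicle tumours such RNA would not raise genes that were no higher in A375 than in A375R alone under vehicle. Yet 10 genes of this kind were higher in mixed tumours. They were GIMAP4, GIMAP6, IL1B, PDE3A, GABRA5, NLRP3, NMNAT2, SULT1B1, COL17A1 and ANKRD33B, listed after their values were seen. At an adjusted p under 0.05 some of the 264 higher calls may be false, and 10 genes are few enough for that. For PDE3A and NLRP3 the levels in A375 and A375R were also close, in tables normalised separately, while in the others they lay further apart. The 10 genes therefore cannot decide whether such RNA was the only source. The authors' size factors are argued against for the 236, of which 203 (86%) stayed past the threshold with quantile normalisation. A change in gene expression of the A375R cells themselves stays open for the 236 and for the 10, and was not tested.

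The glycolysis and hypoxia list was lower in A375R alone under drug (median -0.36) and in mixed vehicle tumours (median -0.333) than in A375R alone under vehicle, a group both comparisons share, by camera at the preset correlation but not with an estimated one (adjusted p = 0.515 and 0.694), and the adjusted p that follow are at the preset one. Without each alone vehicle library in turn the largest camera adjusted p was 0.000279. The medians were -0.219 and -0.215 without replicate 1, smaller falls than with all libraries, and -0.527 and -0.514 without replicate 2. These values argue against 1 odd library as the whole cause. Library size is argued against as the whole cause as well. Of the 3 alone vehicle libraries 2 lay within the range of the other 9 (26884205 to 41989684 reads). The larger camera adjusted p was 5.15e-12 without replicate 2, the one out of that range. With log2 reads per library as a term it was 3.69e-07 (medians -0.371 and -0.396). With quantile normalisation in place of the authors' size factors the medians were -0.286 and -0.27 and the upper quartiles -0.0172 and -0.103 (the larger camera adjusted p 0.0012), which argues against the size factors as the whole cause. An effect of the drug or of the neighbours, or a difference in oxygen supply between tumours, may also account for the lower list and was not tested. Chance differences among the 3 alone vehicle libraries, which both comparisons share, stay open too, as neither call passed with an estimated correlation.

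Other splits of the same libraries were counted. For A375 tumours the real split (9603 genes) was the 1 of 35 with as many, the highest other calling 0. That share is under 0.05, which argues against chance for A375 tumours. For the interaction (397) the real split was 1 of 100 drawn, the highest other calling 296. Those splits exchanged mixed and alone labels within each drug arm, so they test for any difference between mixed and alone tumours. They cannot exclude chance for the interaction itself. For the 3 against 3 designs the 10 splits are too few for a share under 0.05: the real value and highest other were 608 and 0 for A375 at 6 h, 6903 and 0 at 48 h, and 5427 and 0 between the times. They were 109 and 0 for A375R alone, 478 and 0 for A375R mixed, 33 and 1 for mixed against alone under drug and 454 and 0 under vehicle. In the paired A375 comparisons the splits that part as many pairs also called 0.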
